A study of Mus musculus with 4 samples.

How the data were processed

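The deposited files hold UMI counts per gene and cell for 4 libraries of mouse islets, 2 per genotype, with 19074 genes listed in each. Per the labels, the authors used Cell Ranger 3.0.0 with the mm10 genome and Seurat 2.3.4. The deposited cells are already filtered: no cell has fewer than 501 detected genes or more than 9.96% mitochondrial UMIs. Totals per library run from 99156230 to 228515309 UMIs. Genes were matched by symbol to GENCODE vM21 (GRCm38) for coordinates.

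Cells with fewer than 500 genes or over 20% mitochondrial UMIs were to be removed, which removed 0 cells. Doublets were called per library from Scrublet scores at 0.8% per 1000 cells, which removed 283, 273, 150 and 49 cells. Counts were scaled to 10000 per cell and log transformed, 2000 variable genes and 30 principal components were kept, and cells were joined to 15 neighbours and clustered by the Leiden method at resolution 1 without integration of the libraries (scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0). Components and distances were rounded so that the graph does not depend on processor arithmetic. The 18 clusters were named from marker lists of 13 classes; the score margin of 0.1, the rule for a cycling cluster (3 cycle genes among its 10 top genes) and the use of leading hormones only within endocrine cells were set after the clusters were seen.

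UMIs were summed per class and library. Genotypes were compared with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3, in classes with at least 20 cells in every library. The difference between the effects in beta and alpha or delta cells was tested as an interaction with the library as a block. Fold changes are knockout over wild type. Gene lists were tested with camera at a preset correlation of 0.01 and at an estimated one, and with fry (limma 3.58.1); p-values of lists are adjusted over the lists tested in a class. Lists with fewer than 3 measured members (acinar, mesenchymal, T cell and B cell markers in beta cells) were not tested. Class shares were compared by an exact two-sided permutation test. Shares of cells with a UMI were computed after thinning every cell to 2000 UMIs.

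Lists, comparisons and alternatives were fixed before the data were examined, except the scaling of sums by cell number. Named genes follow a fixed rule: Sel1l in each class and a panel of genes in beta cells; in beta cells the 10, elsewhere the 5, largest called changes each way with at least 50 CPM in the higher group and both knockout libraries on the same side of both wild type libraries; up to 3 called members of each list with the smallest p in beta cells; and the 5 smallest p each way for the differences between classes. Sex-linked and mitochondrially encoded genes were not eligible as largest changes. Genes named outside this rule are said to be chosen after their values were seen. A few genes that the rule names were tested and counted but are not reported here by name.

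Alternatives were RLE normalization, library size only, sums scaled by cell number, DESeq2 1.42.0, limma-voom, no filter or a mean of at least 20 counts, hormone genes left out, no doublet removal, at least 1000 genes with under 10% mitochondrial UMIs, classes by leading hormone, Leiden resolutions 0.5 and 2, thinned totals, leaving out each library, and the replicate number as a block. The pipeline was tested on simulated data: at a log2 change of 1 it recovered 98% of changed genes in beta cells, 91% in alpha cells and 75% for the difference between them, with 3.43%, 2.55% and 2.92% false calls. The simulation changed 200 genes with a mean of at least 20 counts, as many up as down, with 1 dispersion for all genes. Both genotypes otherwise had the same composition. It held neither the lower insulin share of knockout beta cells nor as many changed genes, so it does not test the scaling. Raw reads were not used here, so the deleted exons and free RNA in empty droplets were not analysed here. Ductal, cycling, erythroid-like and unnamed clusters were not tested for genotype differences. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9 were used.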

Results

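Pancreatic islets of C57BL/6 mice were profiled with the 10x Genomics single-cell 3′ assay, in which every captured RNA molecule carries a unique molecular identifier (UMI). There were 2 libraries from mice with floxed Sel1L alleles (wild type) and 2 from mice that also express Cre recombinase from the insulin gene Ins1 (knockout). No library came from mice with Cre and intact Sel1L, so effects of Cre and of the deletion cannot be told apart. SEL1L is the adaptor of the ubiquitin ligase HRD1 in endoplasmic reticulum (ER) associated degradation, ERAD, which clears misfolded proteins from the ER. The series asks whether this pathway is needed for beta cells to stay beta cells and to work. The sample labels give an age of 7 weeks and the series text gives 5 weeks. The wild type libraries held 5951 and 5841 cells with 215467602 and 228515309 UMIs in all, and the knockout libraries held 4337 and 2483 cells with 160208775 and 99156230 UMIs. The median cell had 37036 and 40121 UMIs in the wild type libraries and 34578 and 37492 in the knockout libraries. The median cell of the wild type libraries had 3801 and 3875 detected genes, against 5072 and 5271 in the knockout libraries. The median mitochondrial share of UMIs was 2.12% and 2.02% in wild type and 3.67% and 3.63% in knockout cells. The labels do not say whether replicates are separate animals, so every p-value below measures a difference against the spread between these libraries.

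Beta, alpha, delta and PP cells made up most of each library, beside endothelial, mesenchymal, Schwann, macrophage and ductal cells. Beta cells were 58.9% ± 0.477 (SD, n = 2) of wild type and 57.6% ± 1.02 of knockout cells. Alpha cells were 18.1% ± 1.82 and 15.5% ± 3.14, delta cells 8.79% ± 1.0 and 8.57% ± 1.59, and PP cells 3.39% ± 1.05 and 3.98% ± 0.220. Endothelial cells were 2.32% ± 0.193 of wild type and 4.53% ± 1.91 of knockout cells, mesenchymal cells 1.14% ± 0.0612 and 2.43% ± 0.460, and Schwann cells 0.854% ± 0.14 and 1.79% ± 0.137. The endothelial class held 124 and 137 wild type and 133 and 143 knockout cells. Without doublet removal the class named endothelial held 49 and 42 wild type and 51 and 27 knockout cells. These numbers are near those of the cluster that no marker list named, 50 and 41 wild type and 54 and 30 knockout cells. In wild type library 1 the 2 sets held 836727 and 841124 UMIs. The name may therefore have passed to other cells, so that setting does not test the endothelial class used here. Macrophages were 2.21% ± 0.186 and 2.23% ± 0.387, and ductal cells 0.160% ± 0.0987 and 0.274% ± 0.252. An exact two-sided permutation test of 2 libraries against 2 cannot give a p below 0.33, the value it gave for beta, endothelial, mesenchymal and Schwann cells, so this test cannot call any share different. Beta cells of the groups fell into different clusters: clusters 2, 3 and 7 held 94.7% and 96.0% of the beta cells of the wild type libraries, and clusters 9, 10 and 12 held 98.4% and 97.7% of those of the knockout libraries. All 6 clusters are counted as beta cells in what follows.

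Sel1l, the targeted gene (ENSMUSG00000020964, GRCm38 chromosome 12, 91806043 to 91849157, minus strand, 21 exons), was read in every library. Beta cells of the wild type libraries held 34.1 and 32.6 CPM of Sel1l (UMIs scaled to a common total of all UMIs), with exact 95% Poisson intervals of 33.2 to 35.0 and 31.7 to 33.4, and those of the knockout libraries held 44.1 (42.8 to 45.3) and 45.4 (43.9 to 47.0). Per beta cell this was 1.61 and 1.68 Sel1l UMIs in wild type and 1.99 and 2.37 in knockout libraries. With insulin transcripts left out of the total, the values became 105.8 and 102.8 CPM in wild type and 73.1 and 80.7 in knockout beta cells. Relative to the median gene, Sel1l fell by 0.51 (log2, SE 0.0636, adjusted p = 0.00104) in knockout beta cells, and the sign turned to 0.42 with library size only and to 0.40 when each sum was scaled by its number of cells. Sel1l was not called in alpha (log2 change 0.26, adjusted p = 0.0662), delta (0.17), PP (0.43), endothelial (0.57), mesenchymal (-0.10), macrophage (0.16) or Schwann cells (0.62). Reads of a 3′ assay are drawn mostly from the end of the transcript, which in the annotation is the 3′ untranslated part of exon 21 (91806043 to 91809846), so they may lie outside the deleted part, and the labels do not say which exons are deleted. The Sel1l counts therefore do not check the deletion.

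Relative to the median gene, 22 of 32 identity genes were lower in knockout beta cells, and Ppy, Pyy and 30 of 38 ER chaperone genes were higher. With sums scaled by cell number the median gene itself stood at 0.91 (log2). Falls given here in CPM or as folds are therefore smaller per cell, and rises larger. Camera called both lists at a preset correlation and neither at an estimated one (adjusted p = 0.265 for identity and 0.468 for ER chaperone genes). The latter setting has little power with 2 libraries per genotype. Ins1, 1 of the insulin genes of the mouse (chromosome 19, 52264297 to 52265476), fell from a mean of 9531 ± 226 UMIs per beta cell (SD, n = 2) to 2919 ± 652, and Ins2 (chromosome 7, 142678656 to 142743381) fell from 24150 ± 2093 to 17420 ± 2793. The maturity factor Mafa (chromosome 15, 75745490 to 75748228) fell 10.4-fold (log2 change -3.38, SE 0.135, adjusted p = 2.0e-05), from 270.8 ± 8.07 to 26.0 ± 5.01 CPM. The glucose transporter gene Slc2a2 (chromosome 3, 28697903 to 28731359) fell 5.33-fold and Ucn3 (chromosome 13, 3940688 to 3945349), which encodes the peptide urocortin 3 of mature beta cells, fell 5.20-fold. Areg (chromosome 5, 91139599 to 91148432), which encodes the growth factor amphiregulin, rose from 0.248 ± 0.145 to 50.3 ± 1.17 CPM (log2 change 7.65, SE 0.194, adjusted p = 4.4e-06).

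By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6273 of the 14626 genes tested in beta cells changed, 3037 higher and 3236 lower in the knockout, and 820 rose and 556 fell by more than 1 log2 unit. Insulin transcripts took 68.0% ± 0.401 of the UMIs of wild type and 41.7% ± 2.82 of those of knockout beta cells, and every log2 change is given relative to the median gene, after TMM scaling. With library size only, the median gene stood at 0.94 and 97.6% of the 13068 genes called were higher; with sums scaled by cell number the median stood at 0.91 and 97.5% of 12909 were higher. Knockout beta cells also held more detected genes (a median of 5559 ± 189.9 against 4099 ± 49.5) and a higher mitochondrial share (3.69% ± 0.0793 against 1.72% ± 0.0275).

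**Figure D1:**
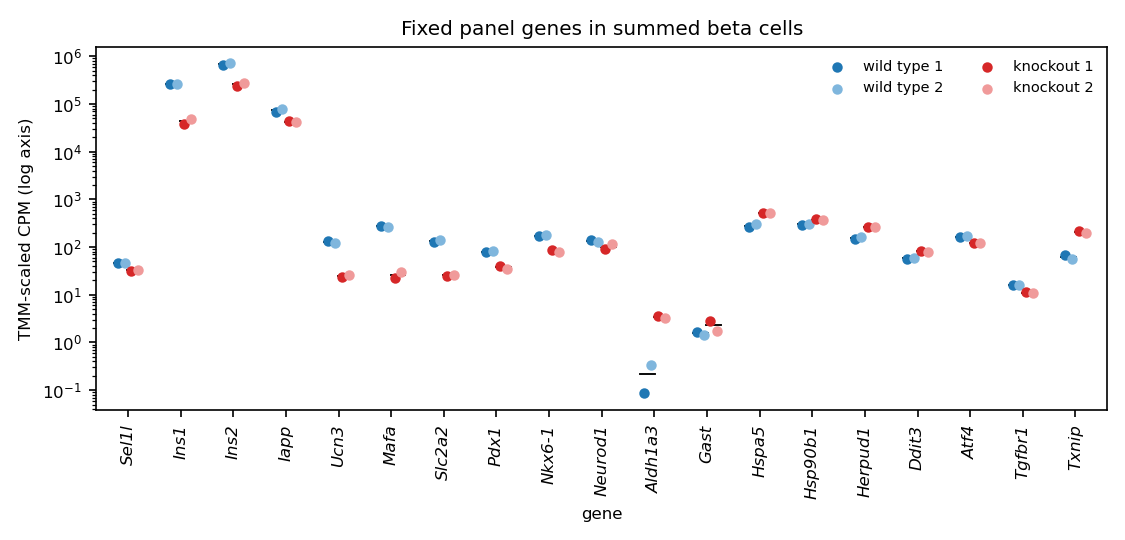
Each reported panel gene in beta cells, as TMM-scaled CPM on a log axis, with 1 point per library (wild type and knockout, 2 each) and a black line at each group mean. Mafa falls from 270.8 to 26.0 and Aldh1a3 rises from 0.214 to 3.48, while Sel1l, Neurod1, Atf4 and Tgfbr1, lower here, are higher in the knockout with library size only or per cell. Iapp, also lower here, is called with neither of those scalings.

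Hormone genes of beta cells did not move alike. Relative to the median gene, Ins1 fell by 2.63 (log2, SE 0.182, adjusted p = 1.2e-04) and Ins2 fell by 1.39 (SE 0.187, adjusted p = 0.00144). In UMIs per cell the log2 ratios were -1.71 and -0.47. Cre is expressed from Ins1 in the knockout mice only. An effect of the Cre allele on Ins1 itself therefore cannot be told apart from that of the deletion. Iapp, which encodes the amyloid peptide released with insulin, fell by 0.80 relative to the median gene. Its mean UMIs per cell were 2642 ± 277.2 in wild type and 2848 ± 83.4 in knockout beta cells. With sums scaled by cell number edgeR did not call it (adjusted p = 0.588), so its fall depends on the scaling. Pyy (chromosome 11, 102106676 to 102107832), the peptide YY gene, rose by 3.47 relative to the median gene (SE 0.279, adjusted p = 2.2e-04). Mean Pyy UMIs per beta cell went from 39.9 ± 1.97 to 815.2 ± 276.9, a log2 ratio of 4.35. Its neighbour Ppy (chromosome 11, 102099930 to 102101319), the pancreatic polypeptide gene, rose by 2.58 relative to the median gene (SE 0.314, adjusted p = 9.7e-04). Mean Ppy UMIs per beta cell went from 38.9 ± 15.1 to 435.0 ± 97.2, a log2 ratio of 3.48. The median beta cell held 6 and 8 Ppy UMIs in the wild type and 101 and 36.5 in the knockout libraries. The median beta cell held 3 and 5 Pyy UMIs in the wild type and 670 and 114.5 in the knockout libraries, against 1, 2, 4 and 2 in the median endothelial cell of the 4 libraries. Gcg, the glucagon gene, was low in beta cells of both groups, with 17.9 ± 0.297 UMIs per cell in wild type and 17.5 ± 7.06 in knockout libraries.

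**Figure D2:**
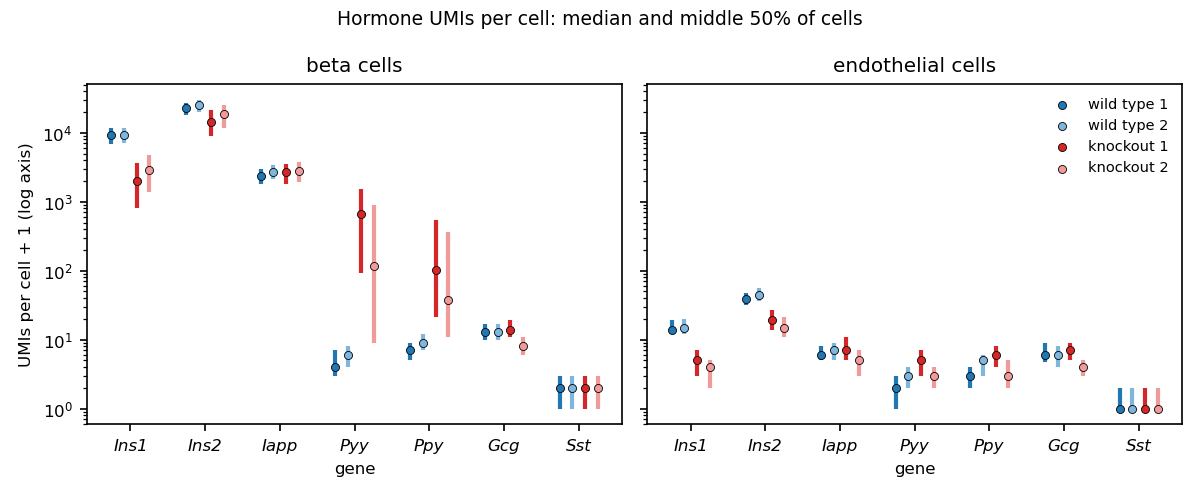
UMIs per cell plus 1, on a log axis, of hormone genes in beta and endothelial cells of each of the 4 libraries; points are medians and bars span the middle 50% of cells. The median Pyy count of beta cells is 3 and 5 in wild type and 670 and 114.5 in knockout libraries, and that of Ins1 is 9145 and 9175 against 1990 and 2874.

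Of the 32 genes fixed as markers of beta cell identity, 22 fell, 2 rose and 8 were not called (2 up and 22 down when adjusted over the list alone; camera adjusted p = 3.4e-24, and adjusted p = 0.265 with an estimated correlation). Pdx1 and Nkx6-1, transcription factors of the beta lineage, fell (log2 changes -1.11 and -1.06). So did the prolactin receptor gene Prlr (-1.85), the granule effector gene Sytl4 (-2.01) and the glucose-6-phosphatase gene G6pc2 (-1.68). Neurod1 fell by 0.40 (SE 0.127, adjusted p = 0.0406) but stood at 0.53 with library size only, and the members that rose, Esrrg and Rfx6 (0.69 and 0.34), are named after their values were seen. With library size only, where the median gene stood at 0.94, the median of the list stood at 0.21 and camera still placed the list lower (adjusted p = 2.3e-11). Ins1, Ins2, Iapp, Nkx6-1, Pdx1, G6pc2, Sytl4, Hadh, Pcsk1 and Ero1lb also served to name the beta clusters. Of 24 hormone granule genes, 13 fell, none rose and 11 were not called (1 up and 13 down adjusted over the list alone; camera adjusted p = 5.1e-07, and adjusted p = 0.265 with an estimated correlation), and with library size only camera still placed them lower (adjusted p = 0.0192). The prohormone convertase gene Pcsk1 fell by 1.53 and Scg3, a granule sorting protein gene, fell by 0.88. Scg3 turns to 0.06 with library size only.

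Of 19 genes of immature, progenitor-like or dedifferentiated beta cells 11 rose, 3 fell and 5 were not called (12 up and 3 down adjusted over the list alone; camera adjusted p = 3.9e-07, and adjusted p = 0.265 with an estimated correlation). Aldh1a3, an aldehyde dehydrogenase gene used as a marker of failing beta cells, rose from 0.214 ± 0.182 to 3.48 ± 0.241 CPM (log2 change 4.01, SE 0.389, adjusted p = 4.3e-04). Neurog3, the endocrine progenitor factor, rose from 0.335 ± 0.0479 to 4.74 ± 0.564 CPM, Dcdc2a rose by 1.58 and Nfatc1 by 1.48. Npy, the neuropeptide Y gene (named after its value was seen), fell by 3.88 and Gast, the gastrin gene, was not called (0.60, SE 0.233, adjusted p = 0.078). Of 18 measured genes that beta cells normally keep off, 5 rose, 1 fell and 12 were not called, the same counts as when adjusted over the list alone (camera adjusted p = 0.144). Oat, an ornithine aminotransferase gene, rose by 2.35 and Parp3 by 2.01.

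Of 38 ER chaperone and unfolded protein response genes 30 rose in knockout beta cells, 2 fell and 6 were not called (32 up and 2 down adjusted over the list alone; camera adjusted p = 3.3e-12, and adjusted p = 0.468 with an estimated correlation). Hspa5, which encodes the ER chaperone BiP, rose from 280.8 ± 26.8 to 523.5 ± 4.64 CPM (log2 change 0.90, SE 0.0899, adjusted p = 4.7e-04). Creld2 rose by 1.10, the protein disulfide isomerase gene P4hb by 0.97, the translocon-associated gene Ssr3 by 0.89 and Hsp90b1 by 0.33, whereas the oxidase gene Ero1lb, named after its value was seen, fell by 1.35. Of 32 ERAD genes, 20 rose, 2 fell and 10 were not called (22 up and 2 down adjusted over the list alone; camera adjusted p = 2.1e-06, and adjusted p = 0.367 with an estimated correlation). Derl3 (chromosome 10, 75893413 to 75895941), a derlin of the ERAD channel, rose from 0.864 ± 0.0992 to 31.5 ± 3.65 CPM (log2 change 5.19, SE 0.125, adjusted p = 4.4e-06). Syvn1, which encodes HRD1 itself, rose by 0.70 and Herpud1 by 0.78. Sel1l is 1 of the 2 ERAD genes that fell, a direction that turns with the scaling.

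Targets of the integrated stress response split: 12 of 34 rose, 16 fell and 6 were not called, the same counts as when adjusted over the list alone (camera adjusted p = 0.517). The median was -0.22 and the mean 0.12, the test pointed down, and with library size only the median was 0.72 with 31 up and 1 down. Ddit3, the gene of the stress factor CHOP, rose by 0.50, the secreted stress protein gene Gdf15 by 1.51 and Nupr1 by 2.88 (from 116.2 ± 73.5 to 857.7 ± 132.0 CPM). Psph and Shmt2, enzymes of serine and glycine synthesis, fell by 1.89 and 1.01. Atf4 fell by 0.45 (SE 0.0691, adjusted p = 0.00240) relative to the median gene, and was 0.49 with library size only. Txnip, an inhibitor of thioredoxin induced by glucose, rose by 1.74.

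**Figure D3:**
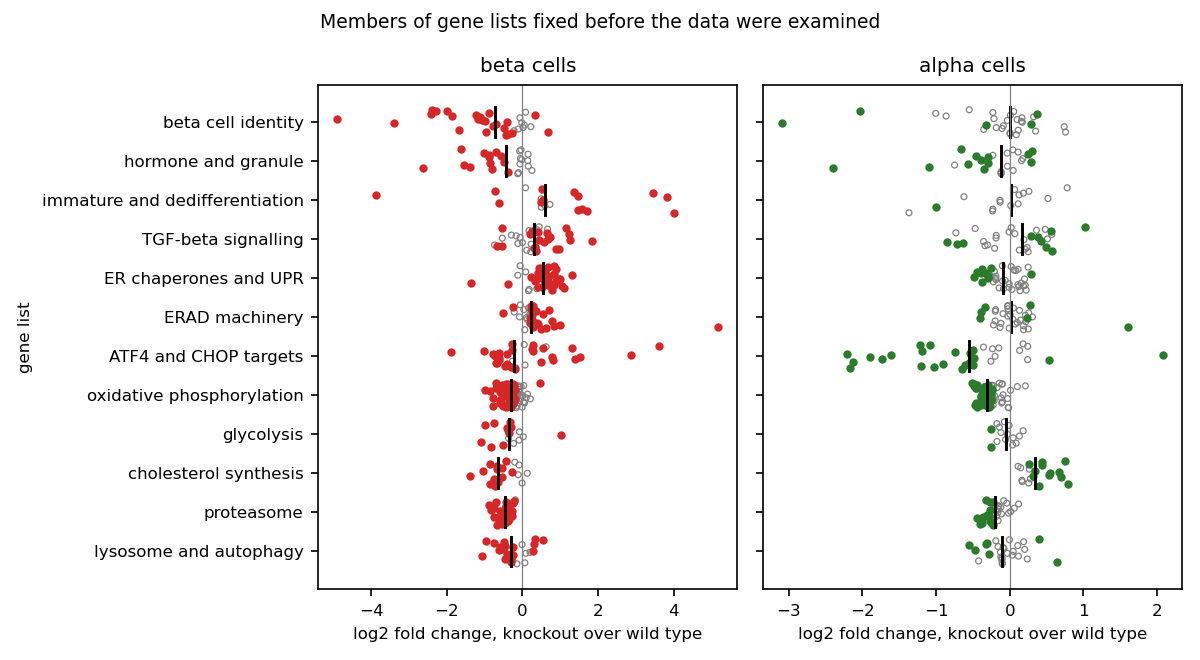
Log2 change, knockout over wild type, relative to the median gene, of every measured member of 12 gene lists in beta cells (red) and alpha cells (green), whose panels have different ranges; filled points have an adjusted p under 0.05, open points do not, and black bars are list medians. In beta cells the medians are 0.54 for ER chaperones and -0.73 for identity genes, and with library size only, where the median gene stands at 0.94, the medians of the lists that lie below 0 in beta cells turn positive.

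Lists of metabolism and protein turnover were tested as well. Of 74 oxidative phosphorylation genes 49 fell, 1 rose and 24 were not called (1 up and 50 down adjusted over the list alone; median -0.30, or 0.64 with library size only; camera adjusted p = 5.7e-07, and adjusted p = 0.468 with an estimated correlation). Of 16 glycolysis genes 10 fell, 1 rose and 5 were not called (1 up and 11 down adjusted over the list alone; median -0.36, or 0.57 with library size only; camera adjusted p = 0.00141, and adjusted p = 0.468 with an estimated correlation). Gapdh fell by 1.08 and Pkm fell by 0.98, while Pdk1, a kinase that inhibits pyruvate dehydrogenase (named after its value was seen), rose by 1.01. All but 1 of 31 proteasome genes fell (0 up and 31 down adjusted over the list alone; median -0.46, or 0.48 with library size only; camera adjusted p = 4.3e-11, and adjusted p = 0.468 with an estimated correlation). Of 27 lysosome and autophagy genes 17 fell, 4 rose and 6 were not called (5 up and 17 down adjusted over the list alone; median -0.30, or 0.64 with library size only; camera adjusted p = 0.00123, and adjusted p = 0.468 with an estimated correlation). The protease gene Ctsb fell by 1.06. Of 19 cholesterol synthesis genes 14 fell, none rose and 5 were not called (0 up and 15 down adjusted over the list alone; median -0.64, or 0.29 with library size only; camera adjusted p = 1.2e-07, and adjusted p = 0.367 with an estimated correlation). Idi1 fell by 1.39 and Msmo1 fell by 1.05. With library size only camera called the cholesterol list, still lower (adjusted p = 0.0259), but not the lists of oxidative phosphorylation (0.775), glycolysis (0.33), proteasome (0.12) or lysosome and autophagy genes (0.775).

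Of 82 ribosomal protein genes 39 rose, 5 fell and 38 were not called (41 up and 5 down adjusted over the list alone; camera adjusted p = 5.8e-06, and adjusted p = 0.468 with an estimated correlation). Rps12 rose by 0.91. Of 13 mitochondrially encoded genes 1 rose and 3 fell (the same adjusted over the list alone; median 0.05, mean -0.13, test down; camera adjusted p = 0.503), and mt-Nd4l fell by 1.33. Of 34 genes of TGF-beta signalling 17 rose, 3 fell and 14 were not called (18 up and 4 down adjusted over the list alone; camera adjusted p = 0.00365, and adjusted p = 0.367 with an estimated correlation and 0.0693 with library size only). Klf10, Skil and Smad7, early targets and inhibitors of the pathway, rose by 1.25, 0.72 and 0.66, whereas the receptor gene Tgfbr1 fell by 0.54 relative to the median gene and was 0.40 with library size only. Of 28 cell cycle genes 2 rose and 7 fell, as adjusted over the list alone (median -0.32; camera adjusted p = 0.453, but 0.0192, lower, with library size only). Ccne1, a cyclin gene, rose by 1.57. Of 17 cell death genes 3 rose and 7 fell, as adjusted over the list alone (median -0.01, or 0.93 with library size only; camera adjusted p = 0.616). Trp53inp1, a target of p53, rose by 0.95 and the pro-apoptotic Bid fell by 1.35. Of 26 antigen presentation and interferon genes 6 rose and 5 fell, as adjusted over the list alone (median 0.05, mean -0.07, test down; camera adjusted p = 0.886). Of 22 immediate early genes, which dissociation of tissue can induce, 6 rose and 4 fell (7 up and 4 down adjusted over the list alone; camera adjusted p = 0.517). Fosb rose by 0.90. None of 5 sex-linked genes was called by edgeR (0 adjusted over the list alone; median -0.06, or 0.88 with library size only; mean 0.03, test down; camera adjusted p = 0.804).

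Markers of other cell types were read in beta cells too. Of 5 PP cell markers 3 rose (4 adjusted over the list alone; camera adjusted p = 0.00322, and adjusted p = 0.468 with an estimated correlation), Ppy, Pyy and Tspan8. With hormone genes left out the list had an adjusted p of 0.370, and with library size only 0.0633. Of 9 alpha cell markers 2 rose and 3 fell, as adjusted over the list alone (median 0.08, mean -0.16, test down; camera adjusted p = 0.453). Ttr fell by 1.88 and Gpx3 rose by 0.84. Of 5 delta cell markers 1 fell, as adjusted over the list alone (median -0.37, or 0.57 with library size only; camera adjusted p = 0.598). The 4 measured haemoglobin genes all rose (4 adjusted over the list alone; camera adjusted p = 0.00365, and adjusted p = 0.468 with an estimated correlation and 0.632 with library size only), Hbb-bs from 0.0510 ± 0.0248 to 1.10 ± 0.358 CPM. A cluster led by haemoglobin genes had been set apart from the beta cells, with 82 and 108 wild type and 31 and 18 knockout cells, in which insulin took 77.9% and 78.3% of wild type and 42.9% and 63.0% of knockout UMIs. The log2 change of Hbb-bs was 4.43, and 4.33 at Leiden resolution 0.5, where this cluster held 45 and 34 wild type and 28 and 17 knockout cells. Where no such cluster was named it was 4.32 with at least 1000 genes per cell and 8.26 without doublet removal. Of 7 macrophage markers 3 fell, as adjusted over the list alone (median -0.60; camera adjusted p = 0.00966, and adjusted p = 0.468 with an estimated correlation and 3.1e-04, still lower, with library size only). Of 5 ductal markers 3 fell (1 up and 3 down adjusted over the list alone; median -0.53, or 0.41 with library size only; camera adjusted p = 0.0902), of 9 endothelial markers 2 rose and 1 fell (camera adjusted p = 0.520) and of 3 Schwann markers 1 fell (median -0.64, or 0.30 with library size only; camera adjusted p = 0.495), each as adjusted over its list alone unless given. Of 28 lists tested in beta cells, 15 passed camera with a preset correlation of 0.01 and 0 with an estimated correlation, while fry called 17. With an estimated correlation camera also allows for the small number of libraries, which leaves it little power. The immature list had an estimated correlation of 0.000912, below the preset one. Its unadjusted camera p still went from 6.9e-08 to 0.0283, so correlation among its genes does not account for the loss.

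Other genes with large changes in beta cells included the long noncoding RNA Snhg18 (up by 2.43), Serping1 (1.68), a complement inhibitor gene, the long noncoding RNA 1810008I18Rik (1.63) and the surface protein genes Cd44 (1.51) and Cd81 (1.48). Dapl1 (log2 change -3.54), the phosphatase inhibitor gene Ppp1r1a (-3.08), Tmem215 (-2.47) and Prss53 (-2.43) fell. The imprinted gene Nnat fell by 4.90 and stood at 60.4 ± 40.0 CPM in wild type and 2.06 ± 0.339 in knockout beta cells, so its size rests on a group with a wide spread. Tmsb15b2 fell by 2.41, though it has a near-identical neighbour and its counts are uncertain.

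The share of beta cells with at least 1 UMI was compared after thinning every cell to 2000 UMIs, which left out 1 and 0 wild type and 9 and 5 knockout beta cells. Mafa was seen in 29.1% ± 1.88 (SD, n = 2) of wild type and 5.95% ± 0.836 of knockout beta cells, against 0.534% and 0.0703% of alpha and 1.82% and 0.207% of endothelial cells of the groups. Slc2a2 was seen in 17.2% ± 0.0212 and 6.21% ± 0.0148, and Ucn3 in 16.4% ± 1.91 and 6.04% ± 0.215, while endothelial shares were at most 0.496% and 0.598%. Trpm5, a cation channel gene, was seen in 5.38% ± 0.698 and 2.02% ± 0.33. Hspa5 was seen in 31.3% ± 2.07 of wild type and 73.9% ± 1.21 of knockout beta cells, against 46.8% and 49.3% of alpha and 62.1% and 57.2% of endothelial cells, and Herpud1 in 19.7% ± 0.742 and 51.1% ± 1.34. Aldh1a3 was seen in 0.0350% ± 0.0263 and 0.883% ± 0.0805, against 0% and 0.0157% of alpha and 0% and 0.0292% of endothelial cells, and without thinning in 0.576% and 15.2% of beta cells. Unthinned shares of beta cells were 90.5% and 54.5% for Mafa, 85.1% and 58.2% for Slc2a2, 87.3% and 55.2% for Ucn3 and 98.5% and 99.8% for Hspa5. Of the 12 genes read this way, 4 (Mafa, Slc2a2, Ucn3 and Trpm5) had lower shares in both knockout libraries than in both wild type libraries. Median depths before thinning were 42634 to 49956.5 UMIs in beta, 17557.5 to 26646.5 in alpha and 5107.5 to 8660 in endothelial cells, and insulin took more of the 2000 UMIs in wild type beta cells. Poisson and Wilson intervals cover counting error only.

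Alpha cells, whose hormone is glucagon, also differed between the groups. Quality measures moved with the groups too: from wild type to knockout libraries the median mitochondrial share (mean of 2 libraries) went from 2.48% to 3.77% in alpha, 2.62% to 3.74% in delta and 1.92% to 2.84% in PP cells, and the median number of detected genes from 3333 to 4489, 3094 to 4098 and 3098 to 4098. Socs3, a brake on cytokine signalling, rose by 0.99 (log2, SE 0.0676, adjusted p = 4.4e-06), Rgs4, a regulator of G protein signalling, by 1.07 (SE 0.120, adjusted p = 2.8e-04), and Lars2, a mitochondrial leucyl-tRNA synthetase gene, by 1.23 (SE 0.0924, adjusted p = 8.1e-06). Crybb3 rose by 1.19 (from 30.1 ± 23.6 to 71.2 ± 25.2 CPM, and 0.81, not called, without knockout replicate 2) and the noncoding RNA Gm42418 by 1.03. Asns, the asparagine synthetase gene, fell by 1.03 (SE 0.0759, adjusted p = 7.2e-06), from 66.7 ± 4.06 to 32.5 ± 1.28 CPM. The inhibitor of DNA binding Id3 fell by 0.85 and the ribosomal protein gene Rpl29 fell by 1.41 (from 788.9 ± 8.33 to 295.9 ± 177.4 CPM). Insulin RNA in the alpha class fell as well. Ins1 fell by 2.40 (SE 0.119, adjusted p = 4.5e-07), from 1788 ± 357.8 to 339.7 ± 13.7 CPM, and Ins2 fell by 1.09. Of 12598 genes tested 2140 changed, 888 higher and 1252 lower, and 898, 23.7% of them higher, by DESeq2. Without wild type replicate 1 the count was 1339, without knockout replicate 1 it was 832 and without knockout replicate 2 it was 861; with library size only the median gene stood at 0.21 and 93.6% of the genes called were higher, and with sums scaled by cell number it stood at 0.76.

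Of 31 integrated stress response genes 20 fell in alpha cells, 2 rose and 9 were not called (2 up and 23 down adjusted over the list alone; camera adjusted p = 3.8e-22, and adjusted p = 0.269 with an estimated correlation). Among members named after their values were seen, Chac1 (-2.13), Gdf15 (-1.89), the translation repressor gene Eif4ebp1 (-1.74) and the folate enzyme gene Mthfd2 (-1.61) fell. The median of the list was -0.55, and 0.20 with sums scaled by cell number. Of 19 cholesterol synthesis genes 12 rose in alpha cells and none fell (14 up adjusted over the list alone; camera adjusted p = 7.9e-12, and adjusted p = 0.872 with an estimated correlation), with Stard4 and Hmgcs1, also named after their values were seen, up by 0.75 and 0.70. Of 74 oxidative phosphorylation genes 50 fell and none rose (1 up and 60 down adjusted over the list alone; median -0.31, -0.10 with library size only and 0.45 per cell; camera adjusted p = 1.8e-16, and adjusted p = 0.36 with an estimated correlation). Of 31 proteasome genes 15 fell and none rose (17 down adjusted over the list alone; median -0.20, and 0.55 per cell; camera adjusted p = 1.6e-06, and adjusted p = 0.36 with an estimated correlation). Of 37 ER chaperone genes 9 fell and 1 rose, as adjusted over the list alone (median -0.09, and 0.12 with library size only; camera adjusted p = 0.343).

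Delta cells shared several of these changes. Bhlhe40, a clock and hypoxia responsive repressor gene, rose by 1.42 (log2, SE 0.141, adjusted p = 2.6e-05), Rgs4 by 1.16, Lars2 by 1.77 and Gm42418 by 1.87. The growth regulator gene Dlk1 fell by 1.90 (SE 0.223, adjusted p = 1.5e-04), from 61.8 ± 24.4 to 16.2 ± 2.91 CPM. Id1 fell by 1.68 and Id3 fell by 1.66, and in the delta class Ins1 RNA (-3.17) and Ins2 RNA (-2.19) were lower. Of 37 ER chaperone genes 18 fell in delta cells and none rose (22 down adjusted over the list alone; median -0.43, -0.28 with library size only and 0.24 per cell; camera adjusted p = 6.5e-16, and adjusted p = 0.391 with an estimated correlation). Of 30 stress response genes 17 fell and none rose (1 up and 18 down adjusted over the list alone; median -0.45, and 0.24 per cell; camera adjusted p = 3.0e-21, and adjusted p = 0.391 with an estimated correlation). Of 11602 genes tested 1131 changed, 457 higher and 674 lower, and 409, 19.3% of them higher, by DESeq2. Without knockout replicate 2 the count was 586; with library size only the median gene stood at 0.16 and 87.9% of the genes called were higher, and with sums scaled by cell number it stood at 0.69.

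In PP cells 149 of 10195 genes changed, 60 higher and 89 lower. Gm42418 rose by 1.79, Lars2 by 1.65, Rgs4 by 1.34 and Dnm3, a dynamin gene, by 1.12 (log2, SE 0.171, adjusted p = 9.6e-04). Sst, the somatostatin gene, fell by 2.42 in the PP class (SE 0.111, adjusted p = 1.6e-11), from 279.6 ± 31.9 to 52.5 ± 0.752 CPM. The median PP cell held 1 Sst UMI in each of the 4 libraries, and the mean was 5.57 and 6.47 in wild type and 1.62 and 2.02 in knockout libraries. Ins1 (-3.34) and Ins2 (-2.59) fell too. Ttr stood at -1.29, but at 971.1 ± 662.5 CPM in wild type against 394.8 ± 36.1, and without wild type replicate 1 it stood at -0.36 and was not called (adjusted p = 0.0574). Mean Gcg UMIs per PP cell also differed between the wild type libraries, 751 and 122.5, with medians of 12 and 11. The count was 72, 25% of them higher, by DESeq2, 274 without wild type replicate 1, 56 without knockout replicate 2 and 995 when cells were assigned by their leading hormone, where Ins2 in PP cells stood at 0.03. The PP class by leading hormone is a mixture: 615 of its cells came from the PP cluster, 241 from the delta, 119 from the alpha and 106 from the beta clusters. With library size only the median gene stood at 0.21 and 93.9% of the genes called were higher, and with sums scaled by cell number it stood at 0.67.

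Among cells that are not endocrine, endothelial cells had 32 genes changed of 8148 tested, 18 higher and 14 lower. Neat1, a nuclear long noncoding RNA, rose by 1.86 (log2, SE 0.174, adjusted p = 0.00249), the von Willebrand factor gene Vwf by 1.59, Sema3g by 1.45, Lars2 by 1.43 and St3gal1 by 1.34. The metallothionein gene Mt1 fell by 3.08 (SE 0.474, adjusted p = 0.0292), from 88.2 ± 61.1 to 10.2 ± 1.69 CPM, and stood at -2.14 without wild type replicate 1. At Leiden resolutions 0.5 and 2 Mt1 stood at -1.67 and -1.09 and was not called (adjusted p = 0.0776 and 0.207). Tfpi2 (-1.79), Rpl29 (-1.52), Gm13889 (-1.4) and the cyclooxygenase gene Ptgs1 (-1.30) fell too. In macrophages 5 genes changed of 7895: Gm42418, the chemokine gene Ccl6, Lars2 and AY036118 rose by 1.65, 1.59, 1.43 and 1.43, and Dcstamp, named after its value was seen, fell by 2.20. No gene was called in mesenchymal or Schwann cells by edgeR, where 514 and 430 genes had an unadjusted p under 0.05; DESeq2 called 12 and 2, and limma-voom 0 and 0. With sums scaled by cell number the median gene stood at 0.55 in endothelial, 0.46 in mesenchymal, 0.87 in macrophage and 0.96 in Schwann cells. The endothelial count was 467, 297, 116 and 15 without wild type replicates 1 and 2 and knockout replicates 1 and 2, and that of macrophages 37, 122, 19 and 3. In the same order the count was 29, 64, 192 and 76 in mesenchymal cells, and 0, 43, 39 and 31 in Schwann cells.

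Several transcripts, named after their values were seen, had changes of the same sign in every class tested, though not called in all of them. Lars2 rose by 0.88 in beta, 1.23 in alpha, 1.77 in delta and 1.65 in PP cells. In the same order the log2 changes of Rpl29 were -1.10, -1.41, -1.39 and -1.36, and those of mt-Nd4l -1.33, -1.05, -0.98 and -0.93. In mesenchymal cells, where they were not called, Lars2 stood at 1.47, Rpl29 at -1.43 and mt-Nd4l at -1.01. Nor were these genes called in Schwann cells, Rpl29 in macrophages, or mt-Nd4l in endothelial cells and macrophages. Gm42418 and AY036118 overlap on opposite strands of chromosome 17 (39846958 to 39848788 and 39847113 to 39848035), and counts of overlapping genes are uncertain. Beta and alpha cells shared 393 higher and 689 lower genes among 12383 tested in both, and 73 and 95 genes were called in opposite directions. Alpha and delta cells shared 242 higher and 484 lower genes, with 0 called in opposite directions among 11295 genes tested in both by edgeR. These classes come from the same 4 libraries, so their calls are not independent.

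The difference between the genotype effects of beta and alpha cells was tested directly, with the library as a block. Among the genes with the smallest p, the log2 change in beta cells minus that in alpha cells was 3.20 (SE 0.122, adjusted p = 1.0e-18) for Kdelr3, which encodes a receptor that returns proteins to the ER, 3.31 for Pyy, 2.28 for Car8 and 2.06 for Txnip. It was -3.92 for Adam32, -3.86 for Dapl1, -3.75 for T2, -2.76 for Vps8 and -1.98 for Maob, a monoamine oxidase gene. For Sel1l it was -0.77 (SE 0.0983, adjusted p = 2.3e-07), but stood at -0.04 with library size only. Of 14400 genes 3982 differed, 1896 toward higher and 2086 toward lower in beta cells, and 2524 without knockout replicate 1. DESeq2 called 1685, and with library size only the median gene stood at 0.71 with 97.5% of the genes called higher. Of the 6131 genes changed in beta cells that this test measured, 2792 (45.5%) also differed from alpha cells in the same direction, 1279 of them higher and 1513 lower.

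By list, the difference (beta minus alpha) was called above 0 for 31 of 38 ER chaperone genes and 15 of 32 ERAD genes, and below 0 for 2 and 3. It was above 0 for 67 of 82 ribosomal protein genes and below 0 for 1, while 39 of these genes rose in beta cells and 6 rose and 15 fell in alpha cells. Of 19 cholesterol synthesis genes 18 had a difference below 0 and none above, with 14 lower in beta and 12 higher in alpha cells (median difference -0.93, and -0.20 with library size only). Of 32 identity genes 20 had a difference below 0 and 2 above (median -0.61, and 0.12 with library size only), and of 31 proteasome genes 19 had one below 0 (median -0.27, and 0.45 with library size only). Against delta cells 2953 of 14486 genes differed, 1519 higher and 1434 lower in beta cells, and 1273 by DESeq2. The difference (beta minus delta) was 7.24 for Bmp3 (SE 0.237, adjusted p = 3.4e-22), 3.67 for Pyy, 2.66 for Ppy, and 2.13 and 1.57 for the ER stress genes Sdf2l1 and Manf. It was -4.63 for Nnat, -3.49 for Ttyh1, -2.49 for Ppp1r1a, -1.48 for Gng12 and -1.38 for the growth factor receptor gene Igf1r. Sel1l stood at -0.67 (SE 0.119, adjusted p = 5.5e-05), and at 0.10 with library size only, where the median gene stood at 0.74 and 98.3% of the genes called were higher.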

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

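All tests of explanations in this part were chosen after the result was seen, except those of a library-wide difference for alpha cells and of another cell type among beta cells.

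The genotype effect differed between beta and alpha cells for 3982 genes, by a test of the difference itself. Among the genes with the smallest p were Kdelr3 (3.20, log2, beta minus alpha), Txnip (2.06), Car8 (2.28) and Pyy (3.31) toward higher in beta cells, and Dapl1 (-3.86), Maob (-1.98), Vps8 (-2.76), Adam32 (-3.92) and T2 (-3.75) toward lower. Sel1l stood at -0.77, and at -0.04 with library size only. Between beta and delta cells 2953 genes differed, among them Pyy (3.67), Bmp3 (7.24), Sdf2l1 (2.13), Ppy (2.66) and Manf (1.57) toward higher, and Ppp1r1a (-2.49), Nnat (-4.63), Gng12 (-1.48), Ttyh1 (-3.49) and Igf1r (-1.38) toward lower. Sel1l stood at -0.67, and at 0.10 with library size only. A cluster that no marker list named held 1.26% of knockout cells, a signal in cells that no comparison above uses; its leading genes include Igfbp5, Mgp, Gng11, Pdgfrb and Col4a2.

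Alpha cells differed between the groups although the deletion is directed at beta cells. Free RNA from beta cells would give alpha cells the changes of beta cells. Of the genes called in alpha cells and measured in beta cells, 78.9% had the sign of their beta change (Wilson interval 77.1 to 80.6). Each sign is relative to the median gene of its own class, whereas per cell 97.5% of the genes called in beta cells were higher. The signs therefore cannot decide on free RNA, which stays open. A difference between the libraries acting on every class could give the changes: endothelial cells showed 90.5% of the median alpha change for the same genes, Schwann cells 73.8%, mesenchymal cells 53.7% and macrophages 30.5%. The labels name no batch, and library and genotype go together, so such a difference and a response of alpha cells to the genotype cannot be told apart. A response of alpha cells to altered beta cells stays open as an untested biological explanation.

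Ppy and Pyy were higher in knockout beta cells, in a ratio of at most 0.591. PP cells, or doublets with them, would bring them in the ratio of PP cells, 2.68 to 3.38. The ratio is of UMIs summed over the class, so it argues against them only as the source of both rises together. They could still give part of the Ppy rise, since Ppy was the leading hormone of 106 cells of the beta clusters. Free RNA is argued against by the median Pyy count of knockout beta cells, which was 9.92 and 26.4 times the number scaled from endothelial cells. Beta cells with more than 333 Pyy UMIs held 75.4% and 78.8% of the median insulin UMIs of the others. These cells came from clusters named with Ins1 and Ins2 among the markers, so their insulin cannot exclude another cell type or doublets with beta cells. Knockout delta cells held means of 1775 and 1800 Pyy and 1714 and 1978 Sst UMIs. Knockout beta cells held only 2.79 and 2.94 Sst UMIs, which argues against delta cells or doublets with them. A library difference alike in fold in beta, alpha and delta cells is argued against by the larger log2 genotype effect in beta cells. It was larger by 2.21 (SE 0.172) and 2.66 for Ppy and 3.31 and 3.67 for Pyy against alpha and delta cells. Mean Ppy UMIs per cell also rose in alpha cells (433.7 and 422.7 to 1202 and 762.5) and delta cells (733.4 and 682.6 to 1201 and 1049). From these higher starting levels, a rise alike in UMIs rather than in fold is not excluded for Ppy. A change of beta cells with the genotype stays a hypothesis, found and tested on the same data. The labels name no batch, and a library difference confined to beta cells was not tested.

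Ins1 and Ins2 were lower in alpha, delta and PP cells of the knockout. Free RNA from beta cells may be the source, since in the cells of each class with at most its median insulin UMIs the ratio of Ins1 to Ins2 was within 25% of that in beta cells in 19 of 20 pairs of class and library, 0.313 to 0.368 in wild type and 0.152 to 0.2 in knockout libraries. Doublets with beta cells would leave the median cell unchanged, but the median Ins1 count was lower in both knockout libraries in 3 of 3 classes, 20 to 27 UMIs in wild type and 5 to 6 in knockout cells. Expression of insulin by these cells was not tested apart from free RNA.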

How the results depend on the processing

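The scaling by UMIs per cell was chosen after the data were seen; all other alternatives were planned. Of 2969 comparisons of a named gene in a class with its value under an alternative (158 results, 19 settings), 2807 counted as unchanged, 95 became weaker, 13 stronger and 54 reversed. For genes of the difference between classes 370 of 375 counted as unchanged (4 weaker, 1 reversed), and for gene lists 224 of 261 (26 weaker, 10 stronger, 1 reversed). These tallies include endothelial genes without doublet removal and PP genes with classes by leading hormone, where the class may hold other cells. A change of direction counted as reversed only where the result was called in at least 1 of the settings compared. Results called in neither could change direction and still count as unchanged. The list of stress response targets, for example, pointed down with TMM and up with library size only.

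Insulin takes a larger part of wild type beta UMIs, so library size only moves the median gene of beta cells to 0.94 and their count to 13068. The counts with library size only were 3525 in alpha, 423 in PP, 216 in endothelial and 1 in mesenchymal cells, and 10069 and 9249 for beta against alpha and delta cells, with 9 lists; the cause was not tested outside beta cells. UMIs per cell gave 12909 in beta, 11060 in alpha, 9009 in delta, 5888 in PP, 3091 in endothelial, 4633 in macrophage and 3879 in Schwann cells.

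These genes fell in beta cells with TMM and were higher with library size only, and then with UMIs per cell: Sel1l 0.42 and 0.40, Iapp 0.14 and 0.11, Neurod1 0.53 and 0.52, Atf4 0.49 and 0.46, Tgfbr1 0.40 and 0.37, Scg3 0.0602 and 0.0316, Ndufc2 0.0740 and 0.0412, Uqcrq 0.25 and 0.22, Ndufa11 0.17 and 0.14, Aldoa 0.10 and 0.0695, Hmgb2 0.51 and 0.48, Mcm6 0.23 and 0.20. Likewise Bax stood at 0.23 and 0.20, Ifi27 0.29 and 0.27, H2-K1 0.44 and 0.41, Ier3 0.17 and 0.13, Sqle 0.0849 and 0.0570, Psmd1 0.19 and 0.17, Psmb3 0.19 and 0.16, Psmd14 0.0642 and 0.0285, Npc2 0.19 and 0.16, Rpl22l1 0.19 and 0.16, mt-Nd5 0.47 and 0.45, Slc7a2 0.48 and 0.45, Sst 0.44 and 0.41, Krt7 0.41 and 0.38. Egfl7 stood at 0.00199 with library size only and was not called. By edgeR, Iapp, Scg3, Ndufc2, Ndufa11, Aldoa, Mcm6, Ier3, Sqle, Psmd14 and Npc2 were called with neither of these scalings. Uqcrq, Bax, Psmd1, Psmb3 and Rpl22l1 were called with library size only but not with UMIs per cell. For genes not called, the positive value shows a lost fall rather than a rise. Sel1l in beta against delta cells stood at 0.10 with library size only, and the oxidative phosphorylation list had an adjusted p of 0.775, upward. Ins2 in PP cells stood at 0.0282 with classes by leading hormone. That PP class held 364 and 176 knockout cells, against 173 and 93 in the main PP class. It drew 615 cells from the PP cluster, 241 from the delta, 119 from the alpha and 106 from the beta clusters. Its Ins2 value is therefore that of a mixture with cells of the beta clusters, not of the PP cluster.

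DESeq2 called 898 genes in alpha, 409 in delta, 72 in PP, 12 in mesenchymal, 24 in macrophage and 2 in Schwann cells, and 1685 and 1273 for beta against alpha and delta cells. Without a filter on low counts 349 genes were called in PP, 318 in endothelial, 147 in mesenchymal, 134 in macrophage and 108 in Schwann cells. With at least 1000 genes per cell the count was 261 in PP, 9 in endothelial and 2 in mesenchymal cells, and with hormone genes left out 1 in mesenchymal cells. Classes by leading hormone gave 995 in PP cells, a class that then mixed cells of several clusters. Leiden resolution 0.5 gave 253 in PP cells and Leiden resolution 2 gave 14 in endothelial cells. Thinned totals gave 4 in endothelial cells and no doublet removal gave 22 in macrophages. Without the library block 2471 and 1597 genes differed for beta against alpha and delta cells. With an estimated correlation, a setting with little power at this number of libraries, 0 lists were called. The difference in the beta share, -1.30 points, was -2.27 and -2.26 at Leiden resolutions 0.5 and 2, -2.72 without doublet removal, -2.36 with at least 1000 genes and -3.46 by leading hormone. The cause was not tested for these changes.

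Leaving out each library in turn leaves an arm with 1 library, which is assumed to vary like the other arm. The counts then ranged from 4844 to 6651 in beta, 832 to 1831 in alpha, 586 to 1231 in delta, 56 to 274 in PP, 15 to 467 in endothelial, 3 to 122 in macrophage, 29 to 192 in mesenchymal and 0 to 43 in Schwann cells. They ranged from 2524 to 3555 and from 2180 to 2329 for beta against alpha and delta cells, from 15 to 17 for lists, and from -2.02 to -0.58 points for the beta share.

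The replicate numbers are shared by the groups, but nothing shows that they pair libraries: the differences between replicates of the groups correlated across genes at -0.025 in beta, -0.039 in alpha, -0.075 in delta and 0.018 in PP cells. With the replicate block 5796 genes were called in beta, 2308 in alpha, 1360 in delta, 195 in PP, 166 in endothelial, 13 in mesenchymal, 77 in macrophage and 0 in Schwann cells by edgeR. The lowest number of cells in a library is 42 for Schwann and 61 for mesenchymal cells, and what depth limits was not tested in the smaller classes. Classes by leading hormone do not apply to classes that are not endocrine.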

Other observations

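The values in this part were chosen after the data were seen.

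Pyy UMIs per cell were higher in alpha and delta cells of the knockout, which held more UMIs of all genes. The median alpha cell held 282 and 333 Pyy UMIs in wild type and 833 and 517.5 in knockout libraries, and the median delta cell 1150.5 and 1297 against 1606.5 and 1597. As a share of UMIs, Pyy took 2.78% and 3.13% in wild type and 4.37% and 3.05% in knockout alpha cells, and 10.0% and 10.6% against 10.1% and 9.38% in delta cells. Relative to the median gene Pyy stood at 0.13 in alpha cells (adjusted p = 0.570) and -0.24 in delta cells (adjusted p = 0.0483). More than 333 Pyy UMIs, the higher of the wild type alpha medians, were found in 3.01% and 2.70% of wild type beta cells (Wilson 95% intervals 2.48 to 3.65 and 2.20 to 3.31) and in 63.2% and 39.9% of knockout beta cells (61.2 to 65.1 and 37.3 to 42.5). In alpha cells the shares were 45.0% and 49.9% against 78.7% and 65.4%, and in endothelial cells 0 of 124, 0 of 137, 0 of 133 and 1 of 143 cells.

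A cluster of cells in division held 1.63% ± 0.659 (SD, n = 2) of wild type and 1.09% ± 0.319 of knockout cells (exact two-sided permutation p = 0.667). A cluster led by haemoglobin genes, with Ins1 and Ins2 also among its leading genes, held 1.69% ± 0.349 and 0.740% ± 0.0006. The cluster that no marker list named held 0.809% ± 0.103 and 1.26% ± 0.0404. A Schwann cluster of 40 cells was led by the heat shock genes Hspa1a and Hspa1b.

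In every class tested except beta cells the median cell held more UMIs in the knockout libraries: the median alpha cell held 18170 ± 863.7 in wild type and 26270 ± 534.2 in knockout libraries, the median delta cell 11940 ± 695.1 and 17260 ± 1120, and the median macrophage 10780 ± 190.6 and 18120 ± 1438. The median PP cell held 22070 ± 113.8 and 30220 ± 1289, the median endothelial cell 5462 ± 501.7 and 7689 ± 1373, the median mesenchymal cell 6536 ± 110.3 and 8650 ± 1100, and the median Schwann cell 9049 ± 215.0 and 14790 ± 742.5. Beta cells held 48190 ± 2226 and 46300 ± 5178, and without insulin 15030 ± 576.6 and 26800 ± 1338.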
